A study of Mus musculus with 3 samples.

How the data were processed

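Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on cerebral cortices of C57BL/6 mouse embryos at E14.5. Per the labels' protocols, tissue was fixed with 2 mM disuccinimidyl glutarate, a protein-protein crosslinker, for 45 min and then with 1% formaldehyde for 10 min, and chromatin was sheared with a Bioruptor sonicator. The series holds 3 libraries: 1 with an antibody against Tbr2 (the T-box transcription factor Eomes), 1 with an antibody against Neurog2 (a basic helix-loop-helix transcription factor) and 1 of input chromatin. Each was used here as a single library, with no replicate.

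The submitters' processing notes name Bowtie 0.12.3, a short-read aligner, MACS 1.4, a peak caller, and the mouse genome build mm9. The roles and settings of these tools, the treatment of duplicate reads and the control used for peak calling are not given in the sources used here. Per the file headers, the tracks were exported from the GeneProf platform. Each ChIP library has 1 list of peaks. No peaks of the input library were used here. For each peak the authors deposited its position and, as text in 1 field, its fold change, FDR, p-value and number of sequence tags. The deposited score column holds the value 750 for every peak in both lists, so it was not used. The planned design assumed a score per peak in that column. The score used instead was computed here as the negative of log10 of the deposited p-value, times 10. Of the Tbr2 peaks, 3 share the smallest p-value, 1e-310, and are tied at a score of 3100.

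The lists end at different limits. The weakest listed Tbr2 peak had a p-value of 9.98e-06 and the highest Tbr2 FDR was 0.0233. For Neurog2 the largest p-value was 8.65e-07 and the highest FDR was 0.1. Total reads per library are not given in the sources used here, so depth is unknown and tags were not scaled between lists. The tags inside peaks summed to 736045 for Tbr2 and 100430 for Neurog2. These sums depend on how many peaks were called and are not library depths. Fold changes, p-values and tags are the authors' own values per peak. They were used mainly to describe or rank peaks within a list. Between the lists, scores, tags and fold changes were correlated across shared sites as ranks and logarithms, and some alternatives applied a common score or p-value limit to the lists.

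Coordinates are mm9 and are given counted from 1. The gene table at hand was of another build, GRCm38.p6. On 7 chromosomes the last peak ended beyond the last gene of that table, by up to 7.04 Mb on chromosome 7, so it was not used with these positions. No mm9 sequence or annotation was used here. The planned shares at promoters, exons and introns, the T-box and E-box motif search and the tests of gene lists fixed beforehand were therefore not run, and peaks are given by position without gene names.

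Peaks of the lists were called shared when they overlapped by at least 1 bp (bedtools 2.31.1). The share of Neurog2 peaks on a Tbr2 peak was compared with 1000 random placements of the Neurog2 peaks, which kept each peak's width and chromosome, between the first and last peak of either list on that chromosome. Assembly gaps were not excluded. These placements give a one-sided p of no less than 0.001. Scores of shared and unshared peaks were compared within each list by the difference of medians, with a two-sided permutation test of 100000 resamples (smallest possible p 1e-05), Benjamini-Hochberg adjustment over the lists and a percentile interval from 1000 bootstrap resamples of peaks. Clusters were peaks stitched across gaps of up to 12.5 kb, and clusters of at least 5 peaks were counted and compared with 1000 random placements. Counts on chromosomes were compared by Fisher's exact test, and over the 19 autosomes by a chi-square test. Intervals of shares are 95% Wilson intervals. They cover counting error over peaks only. With 1 library per factor, every test describes these lists, since peaks are not replicates, and no spread between ChIP experiments could be measured.

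The rule for the regions named in the text was fixed before the data were examined: the 10 highest-scoring peaks of each list, the 10 shared sites with the lowest sum of ranks, and the 5 clusters with the most peaks of each list. For shared sites the rule was written as the highest sum of ranks. Rank 1 is here the strongest peak, so the lowest sum was taken. The score that ranks the peaks was computed from the p-value only after the planned score column was found to be constant. Any other region is named as chosen after its values were seen. The alternatives changed the overlap rule, score limits, list length, peak width, the random placement, the chromosomes used, the measure of strength and the stitching distance. The overlap, median and cluster tests were tested on simulated data with the real widths and chromosomes of the 2640 Neurog2 peaks. With 30% of peaks planted on Tbr2 peaks the excess over placement was 29.7 percentage points, and with 10% planted it was 9.64. With none planted the excess was -0.0608 and the p from placements was 0.672. Unplanted peaks were drawn by the same random placement that the test uses, so this does not show how the test behaves with regionally clustered peaks. A planted shift of 20 in the median score was recovered as 21.5, with no shift the difference was 1.52 (permutation p = 0.711), and all 10 planted clusters were found. The shift was added to every labelled score, so its recovery checks the computation only. The same holds for the planted overlaps and clusters. Planted peaks were centred on Tbr2 midpoints, and the peaks of planted clusters lay well within the stitching distance. These runs used fewer placements and permutations than the tests of the data. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.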

Results

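Binding of Tbr2 and Neurog2 was mapped by ChIP-seq in the cerebral cortex of mouse embryos at E14.5, a stage of embryonic development when excitatory cortical neurons are being produced. Tbr2, encoded by Eomes, is a T-box factor of intermediate progenitor cells, and Neurog2 is a proneural factor that acts in progenitors of the same lineage. The Tbr2 list held 14539 peaks, which covered 10889 kb, and the Neurog2 list held 2640 peaks, which covered 762 kb. Tbr2 peaks had a median width of 703 bp (interquartile range 591 to 840) and a median fold change of 9.58 (7.42 to 14.1). Neurog2 peaks were narrower, at a median of 277 bp (204 to 350), with a median fold change of 11.8 (9.60 to 14.3). The median number of tags per peak was 38 for Tbr2 and 30 for Neurog2. Each factor had 1 library, so no value has a replicate error, and library depth is unknown. The tests below compare these lists, and peaks are not replicates.

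Tbr2 and Neurog2 peaks lay along all 19 autosomes and were sparse on the X chromosome. Tbr2 peaks numbered 6.00 per Mb of spanned autosome, from 4.60 on chromosome 17 to 6.95 on chromosome 4. On the X chromosome there were 1.31 Tbr2 peaks per Mb, and the autosomal density was 4.59 times as high. The Neurog2 list had 1.08 peaks per Mb of autosome and 0.265 per Mb of X, a ratio of 4.06. Among the autosomes, Neurog2 peaks were most frequent on chromosome 4, at 1.49 per Mb, and chromosome 11, at 1.36, and least frequent on chromosome 3, at 0.745.

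The ratio of the lists varied over the autosomes (chi-square 41.2 with 18 degrees of freedom, p = 0.0014). This test treats the lists and their peaks as independent, although 82.5% of autosomal Neurog2 peaks lay on a Tbr2 peak. Its p-value is therefore only a rough guide. Chromosome 11 had 23.2 Neurog2 peaks per 100 Tbr2 peaks, and chromosome 3 had 13.2. For the X chromosome, with 43 Neurog2 and 212 Tbr2 peaks, no difference between the lists was detected by Fisher's exact test (odds ratio 1.13, adjusted p = 0.482). The Y chromosome held 23 Neurog2 and 6 Tbr2 peaks (odds ratio 21.4 against autosomal peaks, Fisher's exact test, adjusted p = 6.29e-14). Of the 23, 14 lay within 113 kb, and the test counts them as separate sites, so its p-value is too small. The Neurog2 peaks on Y had a lower median fold change than autosomal ones, 6.53 against 11.8, and more tags per 100 bp, 27.5 against 11.3. Mitochondrial DNA held 3 Neurog2 peaks, with fold changes of 1.79 to 2.03, and no Tbr2 peak.

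**Figure D1:**
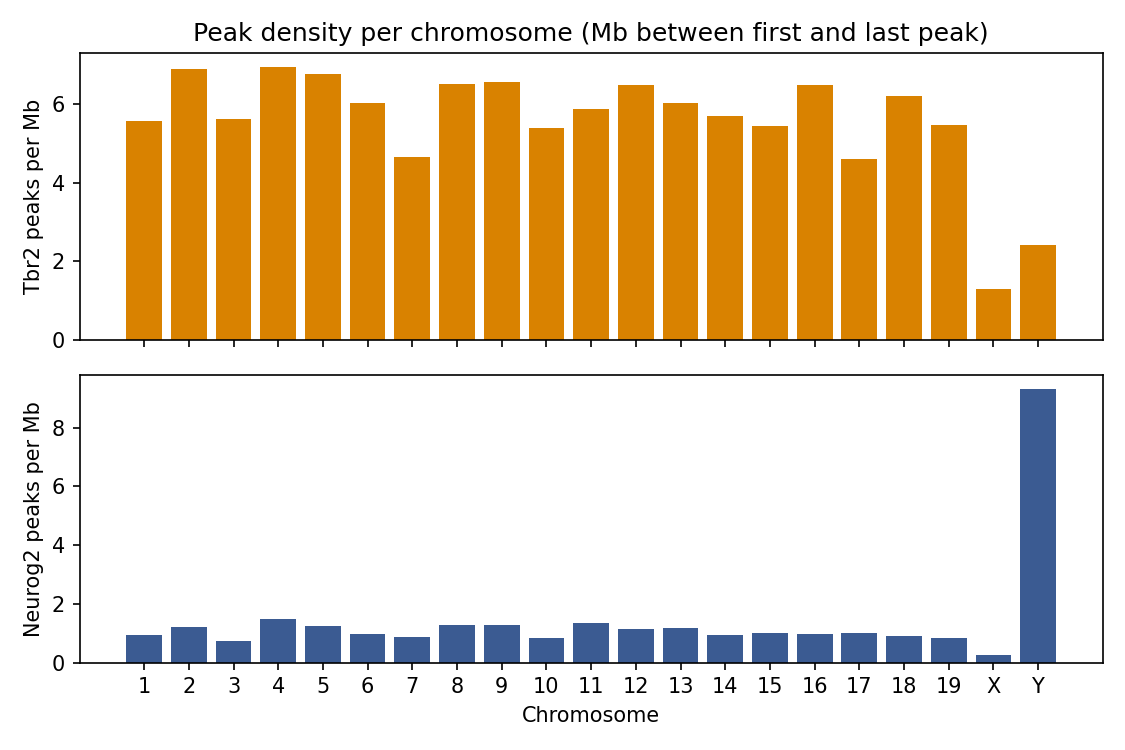
Peaks per Mb of the span between the first and last peak (y axis) on each chromosome (x axis), for Tbr2 (upper bars) and Neurog2 (lower bars), with 1 library each. The X chromosome has 1.31 Tbr2 and 0.265 Neurog2 peaks per Mb, below every autosome, and the Y chromosome has 9.32 Neurog2 peaks per Mb.

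The first comparison was whether the factors occupied the same sites. Most Neurog2 peaks lay on a Tbr2 peak, 2146 of 2640 or 81.3% (95% interval 79.8 to 82.7). Seen from the longer list, 2033 of 14539 Tbr2 peaks, 14.0% (13.4 to 14.6), overlapped a Neurog2 peak, and 12506 did not. Of the shared Tbr2 peaks, 5.16% held more than 1 Neurog2 peak, and none held more than 3. Midpoints in shared pairs were a median of 75.5 bp apart (interquartile range 32.1 to 149), and 83.1% of pairs were within 200 bp.

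Random placement of the Neurog2 peaks put 0.625% of them on a Tbr2 peak (95% of placements between 0.341% and 0.947%), so the observed share was 130.1 times the placed mean. No placement exceeded 1.17% (permutation p = 0.001, one-sided, the smallest that 1000 placements can give). The ratio depends on the background: against Neurog2 peaks displaced by only 5 to 50 kb, which met a Tbr2 peak in 1.74% of cases, it was 46.8. When the Tbr2 list was limited to its 2640 highest-scoring peaks, to match the Neurog2 list in length, 38.4% of Neurog2 peaks (36.6 to 40.3) overlapped it, and 35.6% (33.8 to 37.5) of those Tbr2 peaks overlapped a Neurog2 peak. A reciprocal overlap of 50% was met by 9.28% of Neurog2 peaks. Only peaks of similar width can meet this rule, and Tbr2 peaks were wider at the median, 703 against 277 bp. A Neurog2 peak wholly inside a much wider Tbr2 peak fails it, so the 9.28% mainly reflects widths. Whether both lists were called against the 1 input library is not stated, so a part of the overlap that comes from a shared control cannot be measured here.

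**Figure D2:**
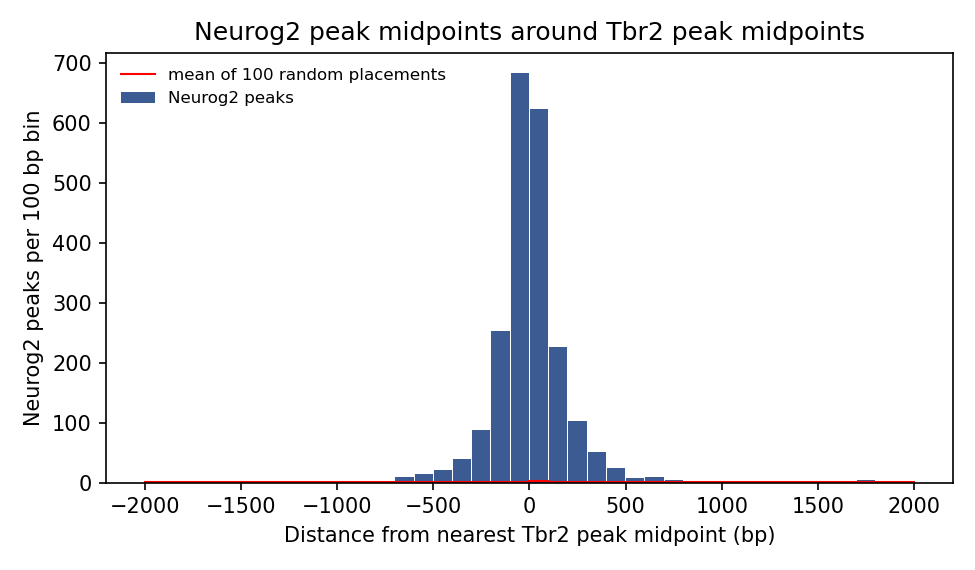
Number of Neurog2 peaks (y axis, bins of 100 bp) by the distance of their midpoint from the nearest Tbr2 midpoint (x axis, bp), with the mean of 100 random placements as a red line. The central bins hold 682 and 622 peaks, and the red line stays below 2 peaks per bin.

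Overlap was less frequent on the sex chromosomes. On the autosomes 82.5% of Neurog2 peaks (81.0 to 84.0) lay on a Tbr2 peak, from 75.5% on chromosome 15 to 88.5% on chromosome 18. On the X chromosome 21 of 43 did, 48.8% (34.6 to 63.2), a lower share than on the autosomes by Fisher's exact test (odds ratio 0.202, p = 6.59e-07). Of the 43 peaks, 8 lay in 1 cluster of 32.8 kb with 3 Tbr2 peaks, and the test counts them as separate sites. Neurog2 peaks on X had a lower median score than autosomal ones, 76.4 against 112, and fewer tags, 18 against 31, but a higher median fold change, 13.4 against 11.8, and more tags per 100 bp, 12.7 against 11.3. On the Y chromosome 3 of 23 overlapped a Tbr2 peak.

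The 494 Neurog2 peaks without a Tbr2 peak were still closer to Tbr2 peaks than placed ones. Leaving out mitochondrial DNA, 127 of 491, 25.9% (22.2 to 29.9), had a Tbr2 midpoint within 10 kb. Random placement gave 9.55% (ratio 2.71, permutation p = 0.001). This placement spans the chromosome and does not keep regional peak density. All Neurog2 peaks displaced by 5 to 50 kb met a Tbr2 peak in 1.74% of cases, against 0.625% when placed at random. Displacement was not run for the unshared peaks alone, so their nearness cannot be told apart from shared peak-rich regions. The median distance to the nearest Tbr2 midpoint was 37.3 kb.

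The second comparison related sharing to the strength of binding within each list. Shared Tbr2 peaks had a median score of 254 against 99.9 for Tbr2 peaks alone, a difference of 154 (95% bootstrap interval 141 to 165). Their median fold change was 13.6 against 9.31 and their median number of tags 71 against 36. Shared Neurog2 peaks had a median score of 121 against 85.8, a difference of 34.7 (29.5 to 40.9), and a median fold change of 12.01 against 10.7. Both differences had a permutation p of 1e-05, the smallest possible, and an adjusted p of 1e-05. Shared peaks were also wider, at medians of 867 against 684 bp for Tbr2 and 287 against 238 bp for Neurog2. Within quartiles of width the score difference was 59.4 for Tbr2 and 24.9 for Neurog2.

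Of the strongest 10% of Tbr2 peaks 43.3% (40.7 to 45.8) overlapped a Neurog2 peak, and of the weakest 10% of the list 3.92% (3.04 to 5.05). The strongest 10% of Neurog2 peaks were shared in 98.9% of cases (96.7 to 99.6), and the weakest 10% in 72.7% (67.1 to 77.7). Each of the 2146 shared Neurog2 peaks was paired with the highest-scoring Tbr2 peak it overlapped. Across these pairs the scores of the factors were weakly correlated (Spearman rho 0.24, Pearson r of log10 scores 0.26). The correlation of tag numbers was 0.32 by Spearman and 0.34 by Pearson, and that of fold changes 0.25 and 0.27. Each of these had a permutation p of 0.0001, the smallest that 10000 permutations can give, and an adjusted p of 0.0001 over the 3 measures. These correlations are across sites, which are not independent replicates.

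**Figure D3:**
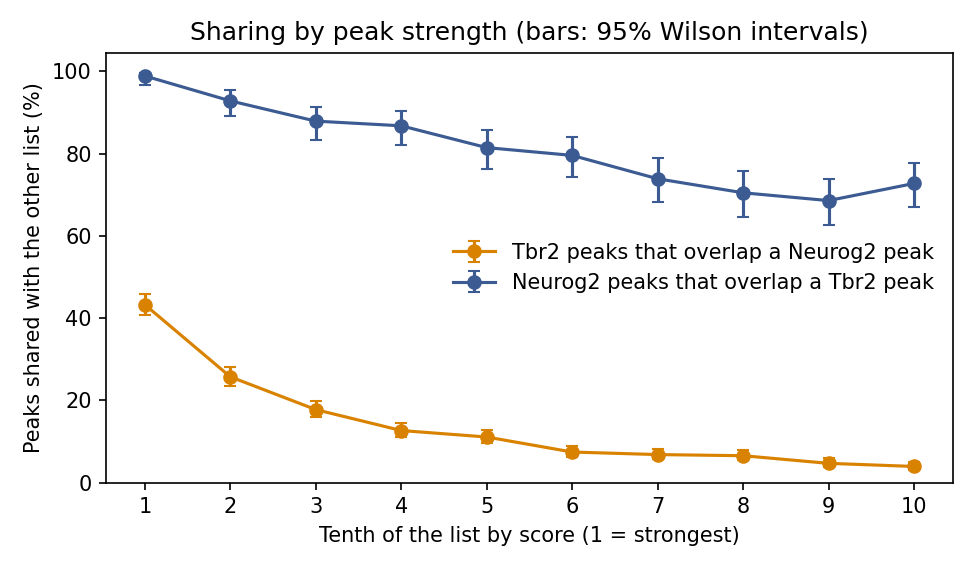
Percent of peaks shared with the other list (y axis) over 10 equal parts of each list, ordered by score with 1 the strongest (x axis), for Tbr2 and Neurog2, with 95% Wilson intervals as bars. Sharing goes from 43.3% in the strongest to 3.92% in the weakest part of the Tbr2 list and from 98.9% to 72.7% for Neurog2.

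Among the 10 highest-scoring Tbr2 peaks, 8 overlapped a Neurog2 peak. The 3 tied at the smallest p-value lay on chromosome 2 at 109800045 to 109801109 (fold change 95.9, 352 tags), chromosome 6 at 55870013 to 55871888 (fold change 62.8, 430 tags) and chromosome 12 at 51220938 to 51224508 (fold change 43.9, 527 tags). The highest fold change of the Tbr2 list, 113, was at the peak of rank 4, on chromosome 2 at 105923751 to 105924631. Shared peaks also stood on chromosome 16 at 77850999 to 77853279 (fold change 30.8), chromosome 15 at 98147397 to 98148392 (70.2) and at 7143965 to 7145586 (83.7), and chromosome 1 at 192121389 to 192122519 (57.0). Peaks without a Neurog2 peak were those on chromosome 3 at 67875091 to 67876571 (fold change 44.6, 351 tags) and chromosome 12 at 119047584 to 119048535 (fold change 55.8, 326 tags).

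All 10 of the highest-scoring Neurog2 peaks overlapped a Tbr2 peak. The first, on chromosome 11 at 114656396 to 114656979, had a score of 1315, a fold change of 38.2 and 179 tags. The second, on chromosome 7 at 119904266 to 119904635, had a score of 798, a fold change of 34.1 and 102 tags. The FDR values of the Neurog2 list imply 8 skipped ranks above the second of these peaks, so this is the order of the listed peaks only. The others lay on chromosome 11 at 118834135, chromosome 4 at 39291289 and 107489918, chromosome 10 at 18996934, chromosome 5 at 111967527, chromosome 16 at 77852495, chromosome 13 at 54419487 and chromosome 3 at 139549326 (starts), with fold changes of 21.3 to 34.0. The Tbr2 peaks under these 10 sites ranked from 6 to 7601, with a median of 1089.5, and 6 of them were in the strongest 10% of the Tbr2 list. The strongest Neurog2 peak outside the Tbr2 list ranked 106, on chromosome 19 at 41809049 to 41809659 (fold change 13.1, 91 tags), and was chosen after its values were seen.

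The shared site with the lowest sum of ranks, 14, was on chromosome 16, where the Neurog2 peak at 77852495 to 77853106 (rank 8, fold change 34.0) lay near the right end of the Tbr2 peak of rank 6, with midpoints 662 bp apart. The next was on chromosome 2, where the Neurog2 peak at 109800352 to 109800881 (rank 18, fold change 26.4) lay 39.5 bp from the midpoint of the Tbr2 peak of rank 1. The remaining 8 of the 10 leading shared sites had midpoints within 114 bp of each other. Their Tbr2 peaks started on chromosome 3 at 139548550 and 38198102, chromosome 12 at 26555534, chromosome 6 at 143943318 and 127650704, chromosome 11 at 43816231, chromosome 17 at 4625908 and chromosome 2 at 72264406. Fold changes at these 8 sites were 30.3 to 99.6 for Tbr2 and 17.9 to 55.4 for Neurog2.

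The third comparison asked where peaks were concentrated. Neighbouring Tbr2 peaks, stitched together, formed 44 clusters of at least 5 peaks, against a mean of 0.499 and at most 4 in random placements (permutation p = 0.001). The placements put each peak independently along its chromosome and so do not keep regional density. Peaks a short way apart also counted separately: on chromosome 14, 1 ended at 9340866 and the next began at 9340985. The excess therefore shows only that peaks were not spread evenly. The 44 clusters held 253 peaks, 1.74% of the list, and 32 of the 44 held a Neurog2 peak. That count was not compared with an expected number, and a region with at least 5 Tbr2 peaks has several places to meet one. Tbr2 peaks in clusters overlapped a Neurog2 peak in 23.7% of cases (18.9 to 29.3) against 13.8% (13.3 to 14.4) elsewhere (Fisher's exact test, odds ratio 1.94, p = 3.16e-05). This test counts the 253 peaks as independent although they come from 44 regions, so its p-value is too small. Peaks in clusters had a median score of 127 against 110.0 elsewhere. The number of clusters was 7 with gaps of up to 5 kb, 163 with gaps of up to 25 kb, and 5 among peaks with a score of at least 100.

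The Tbr2 cluster with the most peaks was on chromosome 9 at 118364273 to 118397192, with 9 peaks in 32.9 kb, fold changes up to 57.3 and 1 Neurog2 peak. Chromosome 14 at 9335848 to 9358678 and chromosome 13 at 83852661 to 83889923 each had 8 Tbr2 peaks, fold changes up to 27.5 and no Neurog2 peak. Chromosome 5 at 132250618 to 132301928 had 7 Tbr2 and 2 Neurog2 peaks, both within the Tbr2 peak with the highest fold change of the cluster. Chromosome 1 at 178859480 to 178882648 had 7 Tbr2 and 4 Neurog2 peaks, and the Tbr2 peak with the highest fold change, 43.1, held 2 of these.

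**Figure D4:**
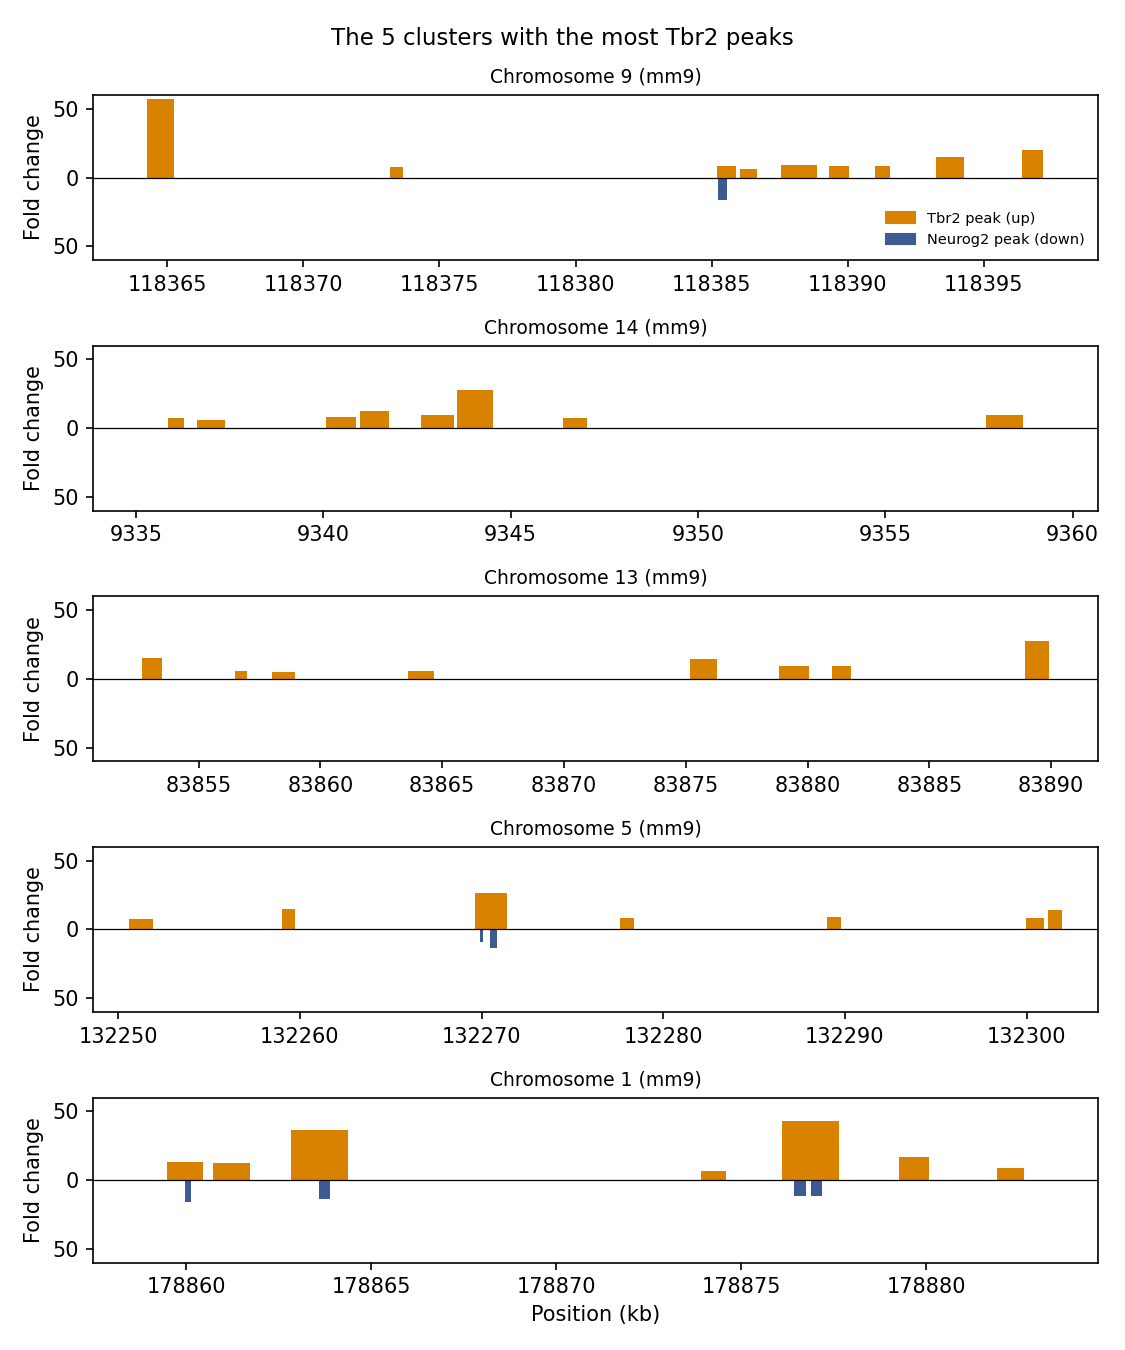
Positions (x axis, kb, mm9) and fold changes (y axis) of Tbr2 peaks (bars up) and Neurog2 peaks (bars down) in the 5 clusters with the most Tbr2 peaks, 1 library each. The clusters on chromosomes 9, 5 and 1 hold 1, 2 and 4 Neurog2 peaks, and those on chromosomes 14 and 13 hold none.

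Neurog2 peaks formed 6 clusters of at least 5 peaks, against a mean of 0.004 in placements (permutation p = 0.001). The limits of placement given for the Tbr2 clusters apply here too. There were 2 with gaps of up to 5 kb, 14 with gaps of up to 25 kb, and 1 among peaks with a score of at least 100. The 3 with most peaks were on the sex chromosomes: X at 121265822 to 121298601 with 8 Neurog2 and 3 Tbr2 peaks, and Y at 2855205 to 2868158 and 2783134 to 2793543 with 6 Neurog2 peaks each and no Tbr2 peak. On the autosomes there were 3 clusters, among them chromosome 13 at 52013061 to 52026026, with 5 Neurog2 and 3 Tbr2 peaks and a fold change of up to 23.3, and chromosome 15 at 82763348 to 82783920, with 5 Neurog2 and 3 Tbr2 peaks and a fold change of up to 13.5.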

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

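The tests on the FDR values, on Y and mitochondrial peaks, on the Tbr2 peaks with the most tags and on the correlation of tags were chosen after the result was seen. The displacement of peaks was added after seeing the data, with its bound set before its own result was seen.

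The FDR values, which no comparison used, imply that 8 ranks are skipped above the second listed Neurog2 peak. The first listed peak has an FDR of 0, which does not fix its rank, so whether the skipped ranks lie above or below it is not known. With 1 control peak, the FDR of 0.1 at the second listed peak corresponds to rank 10, and list place plus 8 gives a whole number of control peaks, to 4 decimals of the FDR, for 2606 of 2640 peaks, against 720 with nothing skipped. If the control peak outscores all skipped peaks, which was not tested, these would carry an FDR of 0.111 to 0.5, and the other end of the list is consistent with a limit of 0.1: the highest FDR among the 100 weakest Neurog2 peaks was 0.0999, against 0.0233 for Tbr2. Loss of peaks at random places is argued against, because 8 skipped ranks gave the best match in each of 3 successive parts of the 600 peaks after the first. Whether the ranks are skipped in the authors' list or only among the peaks analysed here is not known, so another reason for leaving out just these ranks is not excluded, and no biological explanation was tested.

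Neurog2 peaks outnumbered Tbr2 peaks on the Y chromosome relative to the autosomes, with an odds ratio of 21.4, and 3 Neurog2 peaks on mitochondrial DNA held 4037 tags, 4.02% of all tags in Neurog2 peaks. On Y, 14 of the 23 peaks lay within 113 kb, at 2783134 to 2895985. Peaks on Y and mitochondrial DNA had a lower median fold change than autosomal peaks (6.26 against 11.8, difference -5.56, permutation p = 0.0001) and 17.9 more tags per 100 bp (permutation p = 0.0001). Both tests count neighbouring peaks as separate sites, so their p-values are too small. A pile-up of reads from repeated or multicopy sequence could give a lower fold change with more tags per 100 bp. These values come from the Neurog2 list alone. They do not show why the Tbr2 list, from the same tissue, held fewer peaks there. The design gives no biological explanation for that difference, and none was tested. Without Y and mitochondrial DNA, 82.0% of Neurog2 peaks lay on a Tbr2 peak.

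The large share of Neurog2 peaks on Tbr2 peaks was weighed against technical explanations. Peak-rich regions do not account for it: Neurog2 peaks displaced by 5 to 50 kb fell on a Tbr2 peak in 1.74% of cases and in no displacement in more than 2.65%. Tbr2 reads carried into the Neurog2 library are argued against as the only source of the overlap. Of the 100 Tbr2 peaks with the most tags, 67 (95% interval 57.3 to 75.4%) held a Neurog2 peak. Carry-over as the whole source would be expected to put one on nearly all of them. That expectation was not computed, as depths are unknown, and the 8 skipped Neurog2 ranks could add to the 67. Open chromatin or input background common to both libraries cannot be told apart from joint binding, because either would correlate tags across shared sites (rank correlation 0.32), so that this value does not decide, and no peaks of the input library were used here. Binding of both factors to the same sites in the same or in different cells stays open and was not tested.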

How the results depend on the processing

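Displacement by 5 to 50 kb, the common p-value limit (77.6%), the autosomes alone and the fold change in place of the score were chosen after seeing the data. Of 28 alternatives, 21 kept the direction, the side of the threshold and, for counts, stayed within 1.5 times the reported value. The excess of overlap over random placement held under all 12 alternatives for overlap, with permutation p = 0.001 in each, the smallest possible. The share of Neurog2 peaks on a Tbr2 peak was 75.5% to 82.5% under the score limits, fixed width and chromosome choices, 67.5% with midpoints within 200 bp, 38.4% with equal list lengths and 9.28% with a reciprocal overlap of 50%. The reciprocal rule is limited by the unequal widths of the lists. Leaving out peaks wider than 5 kb removed no peak, and so tests nothing. The score differences kept their direction under all 8 alternatives, and the Tbr2 difference was 59.4 within quartiles of width, against 154. The number of clusters depended on the settings by construction. It was 7 for Tbr2 and 2 for Neurog2 with a stitching distance of 5 kb, 163 and 14 with 25 kb, and 5 and 1 with scores of at least 100. With autosomes only, Neurog2 clusters numbered 3 in place of 6, and Tbr2 clusters stayed at 44. Each of these counts exceeded its placements with permutation p = 0.001. Placements within annotation classes or at matched distances to transcription start sites, the test on distal peaks alone, and the alternatives for annotation, motifs and gene lists were not run, as no mm9 genome or annotation was used. Unknown depth limits every statement on unshared sites: a Tbr2 peak without a listed Neurog2 peak may lie under the Neurog2 limit, and the share moves with where a list ends (38.4% against 81.3%).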

Other observations

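All regions and comparisons in this part were chosen after their values were seen. The caller's fold change and its p-value ordered the leading Neurog2 sites differently. The highest fold change of the Neurog2 list, 98.4, was at a narrow peak of 139 bp on chromosome 14 at 104736106 to 104736244, with 57 tags and rank 28 by score. The next, 55.5, was on chromosome 11 at 25000123 to 25000206, with 33 tags and rank 176. Both overlapped a Tbr2 peak. In the Tbr2 list the highest fold changes, 113 and 99.6, were at ranks 4 and 14.

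On the X chromosome, Neurog2 peaks were shared with Tbr2 in 48.8% of cases, with a median score of 76.4. When all Neurog2 peaks were ordered by score in 10 equal parts, parts 8 and 9, with median scores of 79.3 and 70.5 around that value, were shared in 70.5% (64.7 to 75.6) and 68.6% (62.7 to 73.9) of cases, and part 9 had the lowest share of the 10. The difference between X and these parts was not tested.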
